A study of Homo sapiens with 33 samples.

How the data were processed

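T cells positive for CD3 were sorted by flow cytometry from thawed blood mononuclear cells, and libraries were made from 1 to 10 ng of total RNA with a SMART-Seq kit, per the labels' protocols. Such kits amplify cDNA before library construction, so low transcript numbers vary more between libraries. The deposited values are raw read counts per gene, from 0 upward in whole numbers, for 57500 gene rows and 33 libraries, with no normalization. Per the submitters' processing notes, Trimmomatic, STAR 2.5.2b and Subread 1.5.2 were used with the genome build GRCh38. Their roles, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so values of genes with close copies or overlapping neighbours are uncertain. The table's columns were matched to samples by the library number in the labels, and 0 columns were left unmapped. The 485 rows without a symbol held 0.0175% of the counts and were kept under their gene identifiers. Coordinates and gene types come from GENCODE release 29 on GRCh38, in which 15762 of the 15817 tested genes had an entry.

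The day and the patient of each library come from its label. Because each patient gave all 3 days, libraries of a patient are repeated samples of a donor, and the patient was a block in every fit except the alternative without it. The pairing thus comes from the shared donor. As a check, deviations from the day means had a median correlation of 0.429 between libraries of a patient and -0.0905 between patients. In 30 of 33 same-patient pairs the correlation was over 0.1, and 27 of 33 libraries matched their own patient best. No 2 columns were identical, and 0 patients had libraries that disagreed in sex-linked expression. That check cannot find swaps between patients of the same sex or between days of a patient. The patients are the replicates, and no untreated patients were compared, so a difference between days covers everything that changed with time.

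Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM normalization, filterByExpr on the day with its default minimum count of 10 (15817 genes kept), robust dispersion, a quasi-likelihood fit of day and patient over all 33 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values, counts scaled by library size, use the TMM-scaled library sizes. Log2 fold changes are the fit's, with a standard error taken from the F statistic. Gene lists were scored per library as the mean log2 CPM (prior count 2) of their members that passed the filter, for lists with at least 3 such members. Of 33 fixed lists 32 could be scored, and the neutrophil list could not. The change per patient was tested with a two-sided exact sign-flip test over all 2048 sign patterns, adjusted over the lists of a comparison. The smallest p it can give is 0.000977. Camera from limma 3.58.1 was run with a preset correlation of 0.01 and with an estimated one. The CD8A to CD4 ratio was tested with the same sign-flip test, adjusted over 3 comparisons.

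The gene lists, the main tests and a rule for the genes named in the text were fixed before the data were examined. The rule takes a panel of 18 T cell genes whatever their p. It adds, per direction, the 8 called genes with the largest fold change (5 for day 28 vs day 14) that reach a mean of 10 CPM on either day and move the same way in at least 9 of 11 patients. It leaves out unnamed, clone-based and pseudogene entries, receptor and immunoglobulin segments, donor-specific HLA genes and sex-linked marker genes. For each called list it takes up to 4 members. Genes outside the rule are marked as such where they appear.

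Alternatives were no patient block, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a minimum count of 50, limma voom with sample quality weights, fits to the libraries of 2 days alone, no robust dispersion and each patient left out. Lists were also scored with scaled members, and the ratio with other pseudocounts, with CD8B and without pairing (100000 permutations). After the data were seen, 2 alternatives were added, one without the 4 libraries in which MALAT1 took over 6% of counts and one with the MALAT1 share as a covariate. The count test was checked on simulated data of 15817 genes, of which 100 were changed 2-fold and 100 changed 4-fold. For day 14 vs day 0 it recovered 58% of genes changed 2-fold and 92% of those changed 4-fold, with 7 false calls among 157. For day 28 vs day 0 the shares were 52% and 93%, with 11 false calls among 156, and for day 28 vs day 14 they were 55% and 95%, with 7 among 157. These draws were independent for every gene and library, without differences between libraries such as the MALAT1 share. The shares and false calls hold for such data and may be too favourable for the real libraries. A simulated list with no change had an unadjusted sign-flip p under 0.05 in 5.6% of 500 draws, and one shifted by 1 SD in 84%. Lists in the text pass at a p adjusted over the lists, which is stricter, so 84% overstates the power of that test. With 6087733 to 17969966 counts per library, a transcript at 1 CPM rests on about 6.09 to 18.0 counts, so genes near that level carry large counting error. Clinical response and other details of the patients were not used here, and 1 test of a source of the immunoglobulin transcripts is not reported here.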

Results

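Gene expression was measured by RNA sequencing in CD3-positive T cells sorted from the blood of 11 patients with pediatric acute lymphoblastic leukemia who received blinatumomab by continuous infusion. Blinatumomab is a bispecific antibody construct that binds CD3 on T cells. Each patient gave 3 libraries, 1 from before the infusion (day 0) and 1 each from days 14 and 28, so that 33 libraries fell into 3 groups of 11. The counts assigned to genes ranged from 6087733 to 17969966 per library and averaged 13477104 ± 3130216 on day 0, 13628163 ± 2091825 on day 14 and 13307838 ± 2362706 on day 28 (SD, n = 11 each). The first principal component of log2 CPM (counts scaled to library size) held 19.5% of the variance. The patient accounted for 0.941 of the variance along it and the day for 0.00333. MALAT1, a nuclear noncoding RNA, took over 6% of the counts in 3 of 11 day 0 libraries (replicates 3, 8 and 10), 0 of 11 day 14 libraries and 1 of 11 day 28 libraries (replicate 7).

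The comparison of day 14 with day 0 asked how T cell expression differed after 14 days of infusion. LAYN, which encodes the hyaluronan receptor layilin, rose from 7.82 ± 15.6 to 34.5 ± 22.6 CPM (SD, n = 11), a log2 fold change of 2.82 ± 0.45 (SE). HAVCR2, the gene of the inhibitory receptor TIM-3, rose from 22.2 ± 17.7 to 68.3 ± 28.8 CPM (log2 fold change 1.76 ± 0.31), and CTLA4, an inhibitory receptor that competes with CD28 for its ligands, from 52.3 ± 30.0 to 114 ± 39.1 CPM (1.22 ± 0.23). The transcription factor gene MYB rose from 16.6 ± 14.2 to 64.7 ± 49.4 CPM (1.90 ± 0.39). Each of these was higher in 10 of 11 patients. JCHAIN, the joining chain of secreted immunoglobulins, fell from 67.3 ± 184 to 0.428 ± 0.274 CPM, with medians of 2.89 and 0.477 CPM. It was lower in 9 of 11 patients, higher in 1 and without counts on both days in 1. The highest day 0 library carried much of the day 0 mean for JCHAIN, which was 11.9 CPM without replicate 10 (log2 fold change -3.91 without that patient against -4.81), and for LAYN, which was 3.19 CPM without replicate 9 (3.21 against 2.82).

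Of 15817 genes tested, 18 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and the patient as a block, 17 higher and 1 lower on day 14. With no filter on low counts 110 genes were higher and 70 lower, 43 of the lower being immunoglobulin genes, and DESeq2 called 41 higher and 9 lower. At an unadjusted p under 0.05 edgeR's test with the filter gave 1255 genes, against 790.8 expected of unchanged genes, and 17 of 99 random swaps of the days within patients gave as many. The adjusted p was 0.00434 for LAYN, 0.00999 for HAVCR2, 0.0155 for CTLA4, 0.034 for MYB and 0.00695 for JCHAIN. Also higher were LYST, a regulator of lysosome traffic (107 to 210 CPM, adjusted p 0.00434), and the small GTPase gene RAB37 (67.4 to 137 CPM, adjusted p 0.0113). MAGEH1 (33.9 to 73.4 CPM, adjusted p 0.0108) and C1orf228 (54.6 to 107 CPM, adjusted p 0.00999) completed the genes that the selection rule named, and the last 2 and RAB37 were higher in 11 of 11 patients. In GRCh38 coordinates, LAYN (ENSG00000204381) lies on chromosome 11 from 111540280 to 111561745, HAVCR2 (ENSG00000135077) on chromosome 5 from 157085832 to 157142869, CTLA4 (ENSG00000163599) on chromosome 2 from 203867771 to 203873965, MYB (ENSG00000118513) on chromosome 6 from 135181315 to 135219173 and JCHAIN (ENSG00000132465) on chromosome 4 from 70655541 to 70681817. All 5 are annotated as protein-coding, and the values are counts per gene.

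The remaining called genes fell outside the naming rule and are given after their values were seen. GPC3, a membrane proteoglycan gene, had the smallest adjusted p (0.00158), with 1.67 ± 1.59 CPM on day 0 and 9.33 ± 8.31 on day 14. VSIG4 (log2 fold change 3.34 ± 0.57), MYO1E (1.78 ± 0.29) and MRC2 (1.66 ± 0.33) stayed under 10 CPM on both days. AFF3 (0.92 ± 0.16), GPR18 (0.79 ± 0.14) and TSPAN17 (0.94 ± 0.20) were more abundant. SIRPB3P is a pseudogene and ITGB2-AS1 lies antisense to ITGB2. The values of these 2 are uncertain, as reads of related or overlapping genes may be counted with them. Neither the strand setting of the counting nor the treatment of reads that map to several places is given in the sources used here.

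**Figure D1:**
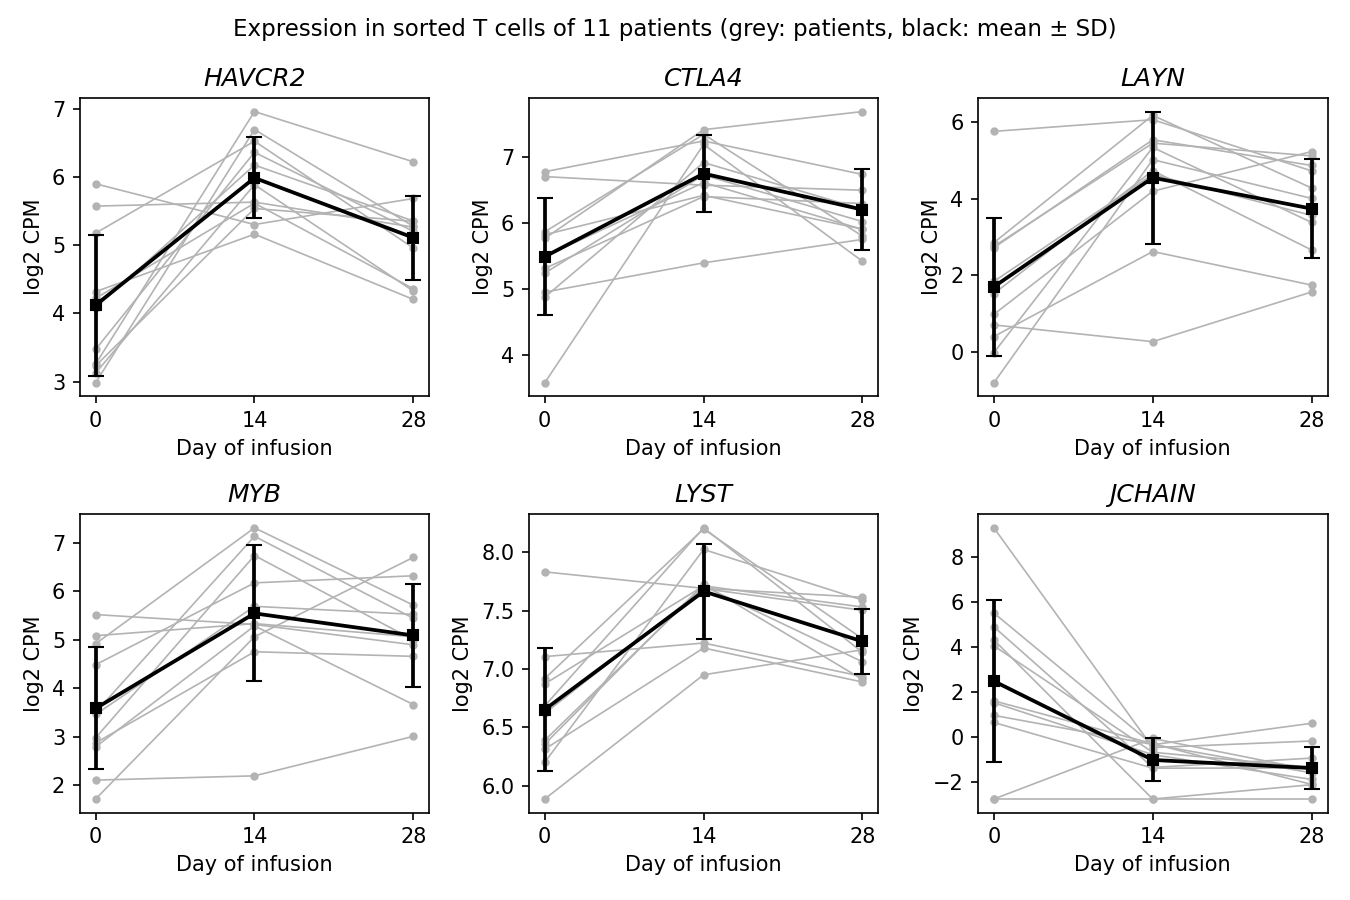
Expression of 6 genes in sorted T cells, as log2 CPM with a prior count of 2 (vertical axis, a different range in each panel), by day of infusion (horizontal axis); grey lines join the 3 libraries of a patient and black squares with bars give the mean ± SD of 11 patients. HAVCR2, CTLA4, LAYN, MYB and LYST were higher on day 14 than on day 0 in 10 of 11 patients each, while JCHAIN was lower in 9 of 11.

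Without the 4 libraries of high MALAT1 share, a check chosen after the data were seen, 9 genes passed and 8 of the 18 remained. LYST, MAGEH1, C1orf228 and JCHAIN were among those kept, while edgeR's adjusted p became 0.135 for HAVCR2 (log2 fold change 1.45), 0.0536 for CTLA4 (1.14), 0.056 for LAYN (2.64), 0.288 for MYB (1.82) and 0.056 for RAB37 (0.86). Over 21 alternatives, each patient left out included, the highest adjusted p was 0.0432 for LYST, 0.135 for HAVCR2, 0.331 for CTLA4, MYB and RAB37, and 0.422 for LAYN. With no block for the patient LYST, JCHAIN and GPC3 passed, and the adjusted p was 0.0601 for HAVCR2, 0.331 for CTLA4 and MYB and 0.422 for LAYN. JCHAIN did not pass in limma voom with sample weights (adjusted p 0.151) or in edgeR's fit to the libraries of the 2 days alone, which called LYST, VSIG4, GPC3, LAYN, MYO1E and RAB37, all of them higher. Leaving out a patient gave between 10 genes (without replicate 4 or 5) and 27 (without replicate 2).

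Of the 12 inhibitory receptors in the fixed list, HAVCR2 and CTLA4 passed the test and 9 had a positive fold change. The same 2 passed when p-values were adjusted over the list alone. LAG3 stood at a log2 fold change of 0.85 ± 0.32 (adjusted p 0.626), PDCD1, which encodes PD-1, at 0.30 ± 0.26 (adjusted p 0.759) and TIGIT at 0.29 ± 0.23 (adjusted p 0.74), none of which passed edgeR's test. The mean log2 change of the list was 0.46 ± 0.54 (SD over patients), positive in 10 of 11 patients, and it did not pass (exact p 0.0186, adjusted p 0.099 over the lists). Without the libraries of high MALAT1 share it was 0.31. Of 16 measured genes of the exhaustion programme other than these receptors, LAYN passed over all genes. LAYN, TOX, IRF4, CD200 and TNFRSF9 did so adjusted over the list alone, with log2 fold changes of 2.82, 0.68, 0.66, 0.73 and 0.93. The list's mean change of 0.42 ± 0.43 was positive in 9 of 11 patients and did not pass (adjusted p 0.0688).

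Among 32 measured lists, 2 passed a two-sided exact sign-flip test over the 11 patients with Benjamini-Hochberg adjustment, and both were higher on day 14. In a camera set test, which compares a list with all other genes, both lists had an adjusted p = 0.193 with an estimated correlation. The regulatory T cell genes rose by a mean log2 of 0.30 ± 0.29 (SD), in 11 of 11 patients (exact p 0.000977, the smallest that 11 patients can give, adjusted p 0.0313). CTLA4 was the 1 member of 11 to pass the gene test, over all genes and adjusted over the list alone, and 5 of the 11 stand also in other lists. FOXP3, the master regulator of that lineage, stood at 0.31 ± 0.23 (adjusted p 0.714) and TNFRSF1B at 0.30 ± 0.21 (adjusted p 0.71). The costimulatory receptors rose by 0.38 ± 0.31, in 10 of 11 patients (adjusted p 0.0469). All 11 members had a positive fold change, 6 of them stand also in other lists, and 0 passed edgeR's test over all genes or adjusted over the list alone, with CD28 at 0.51 ± 0.18, SLAMF6 at 0.86 ± 0.35, TNFRSF9 at 0.93 ± 0.35 and CRTAM at 0.63 ± 0.25. Neither list passed without the libraries of high MALAT1 share (mean change 0.32 and 0.42, adjusted p 0.125 for both, with 8 patients and a smallest exact p of 0.00781), nor without pairing by patient (adjusted p 0.424 and 0.40). With 8 patients a list cannot pass alone among 32, so the first loss does not show that the libraries of high MALAT1 share carried the changes. Over the alternatives the adjusted p ran from 0.0202 to 0.424 for the regulatory T cell genes and from 0.000941 to 0.40 for the costimulatory receptors.

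Other genes of T cell identity and function did not pass edgeR's test. CD3E, a chain of the T cell receptor complex, differed by a log2 of 0.06 ± 0.13, TCF7, a factor of naive and memory T cells, by 0.19 ± 0.17, and CCR7, a lymph node homing receptor, by 0.11 ± 0.27. The granzyme gene GZMK stood at 0.84 ± 0.23, higher in 10 of 11 patients (adjusted p 0.371), GZMB at 0.12 ± 0.32 and the perforin gene PRF1 at 0.40 ± 0.29. The activation marker CD38 stood at 0.79 ± 0.27 (adjusted p 0.577), IFNG at -0.07 ± 0.34, the interleukin 7 receptor gene IL7R at -0.43 ± 0.20 (adjusted p 0.626) and the proliferation marker MKI67 at -0.34 ± 0.47. The cell cycle list differed by 0.01 ± 1.1, was higher in 6 of 11 patients and had a median member fold change of -0.13. Without the libraries of high MALAT1 share its difference was -0.29, of the opposite sign. The cytotoxic effector list differed by 0.20 ± 0.54 (adjusted p 0.392), or by 0.063 without those libraries, the interferon response list by 0.26 ± 0.58 (adjusted p 0.318) and the ribosomal protein list by -0.46 ± 0.77 (adjusted p 0.18), or by -0.11 without them.

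Markers of cells that the CD3 gate should remove were measured beside the T cell genes. The mature B cell markers differed by a mean log2 of -0.50 ± 0.53, lower in 10 of 11 patients (exact p 0.0107, adjusted p 0.0688), with IGHM, the heavy chain of IgM, at -2.24 ± 0.49 (adjusted p 0.0694). The monocyte markers differed by 0.34 ± 0.85 (adjusted p 0.392), or by 0.52 without the libraries of high MALAT1 share, and the dendritic cell markers by -0.42 ± 0.66 (adjusted p 0.18). The immature B cell and lymphoblast list differed by 0.45 ± 0.41 (adjusted p 0.0521). It had 4 measured members, of which MYB rose, while CD79A stood at 0.23 ± 0.19, SOX4 at 0.07 ± 0.29 and CD9 at -0.50 ± 0.23. The mean change within patients did not pass for the MALAT1 share (4.57% on day 0, 3.63% on day 14) or the mitochondrial share (2.31% and 1.85%). The adjusted p was 0.775 for both by the exact sign-flip test.

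The comparison of day 28 with day 0 asked the same after 28 days. JCHAIN again was lower, at 0.332 ± 0.398 CPM against 67.3 ± 184 on day 0 (SD, n = 11), a log2 fold change of -5.66 ± 0.80 with lower values in 9 of 11 patients and medians of 0.213 and 2.89 CPM. Without replicate 10 the fold change was -4.88 and the day 0 mean 11.9 CPM. HAVCR2 stood at 37.3 ± 16.1 CPM, against 22.2 ± 17.7 on day 0 (log2 fold change 0.82 ± 0.30), and CTLA4 at 80.8 ± 44.9 CPM, against 52.3 ± 30.0 (0.65 ± 0.23). Neither passed the test. LAYN stood at a log2 fold change of 1.93 ± 0.44 (adjusted p 0.342) and MYB at 1.41 ± 0.38 (adjusted p 0.764).

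JCHAIN was the 1 gene of 15817 that passed edgeR's test (adjusted p 0.00292), and 569 genes had an unadjusted p under 0.05, below the 790.8 expected of unchanged genes. DESeq2 called 9 genes, with JCHAIN among them, and limma voom with sample weights VSIG4 and GPC3 but not JCHAIN (adjusted p 0.418, the highest of 20 alternatives, of which 19 called it). Of the fixed panel of T cell genes, LAG3 stood at 0.66 ± 0.32, TOX at 0.45 ± 0.21, GZMK at 0.53 ± 0.24, PDCD1 at 0.24 ± 0.26, CD8A at -0.31 ± 0.18 and GZMB at -0.36 ± 0.31, each with an edgeR adjusted p of 0.999. No list passed, by the sign-flip test or by camera with an estimated correlation. The inhibitory receptors differed by 0.32 ± 0.65 (adjusted p 0.693), or by 0.21 without the libraries of high MALAT1 share, and the regulatory T cell genes by 0.13 ± 0.32 (adjusted p 0.693). The plasma cell markers differed by -1.01 ± 0.98, lower in 10 of 11 patients (exact p 0.00684, adjusted p 0.219), with 1 of 6 members called over all genes and 3 adjusted over the list alone. The mature B cell markers differed by -0.55 ± 0.70 (adjusted p 0.344) and the erythroid markers by -1.85 ± 3.28 (adjusted p 0.693), or by -0.88 without those libraries.

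**Figure D2:**
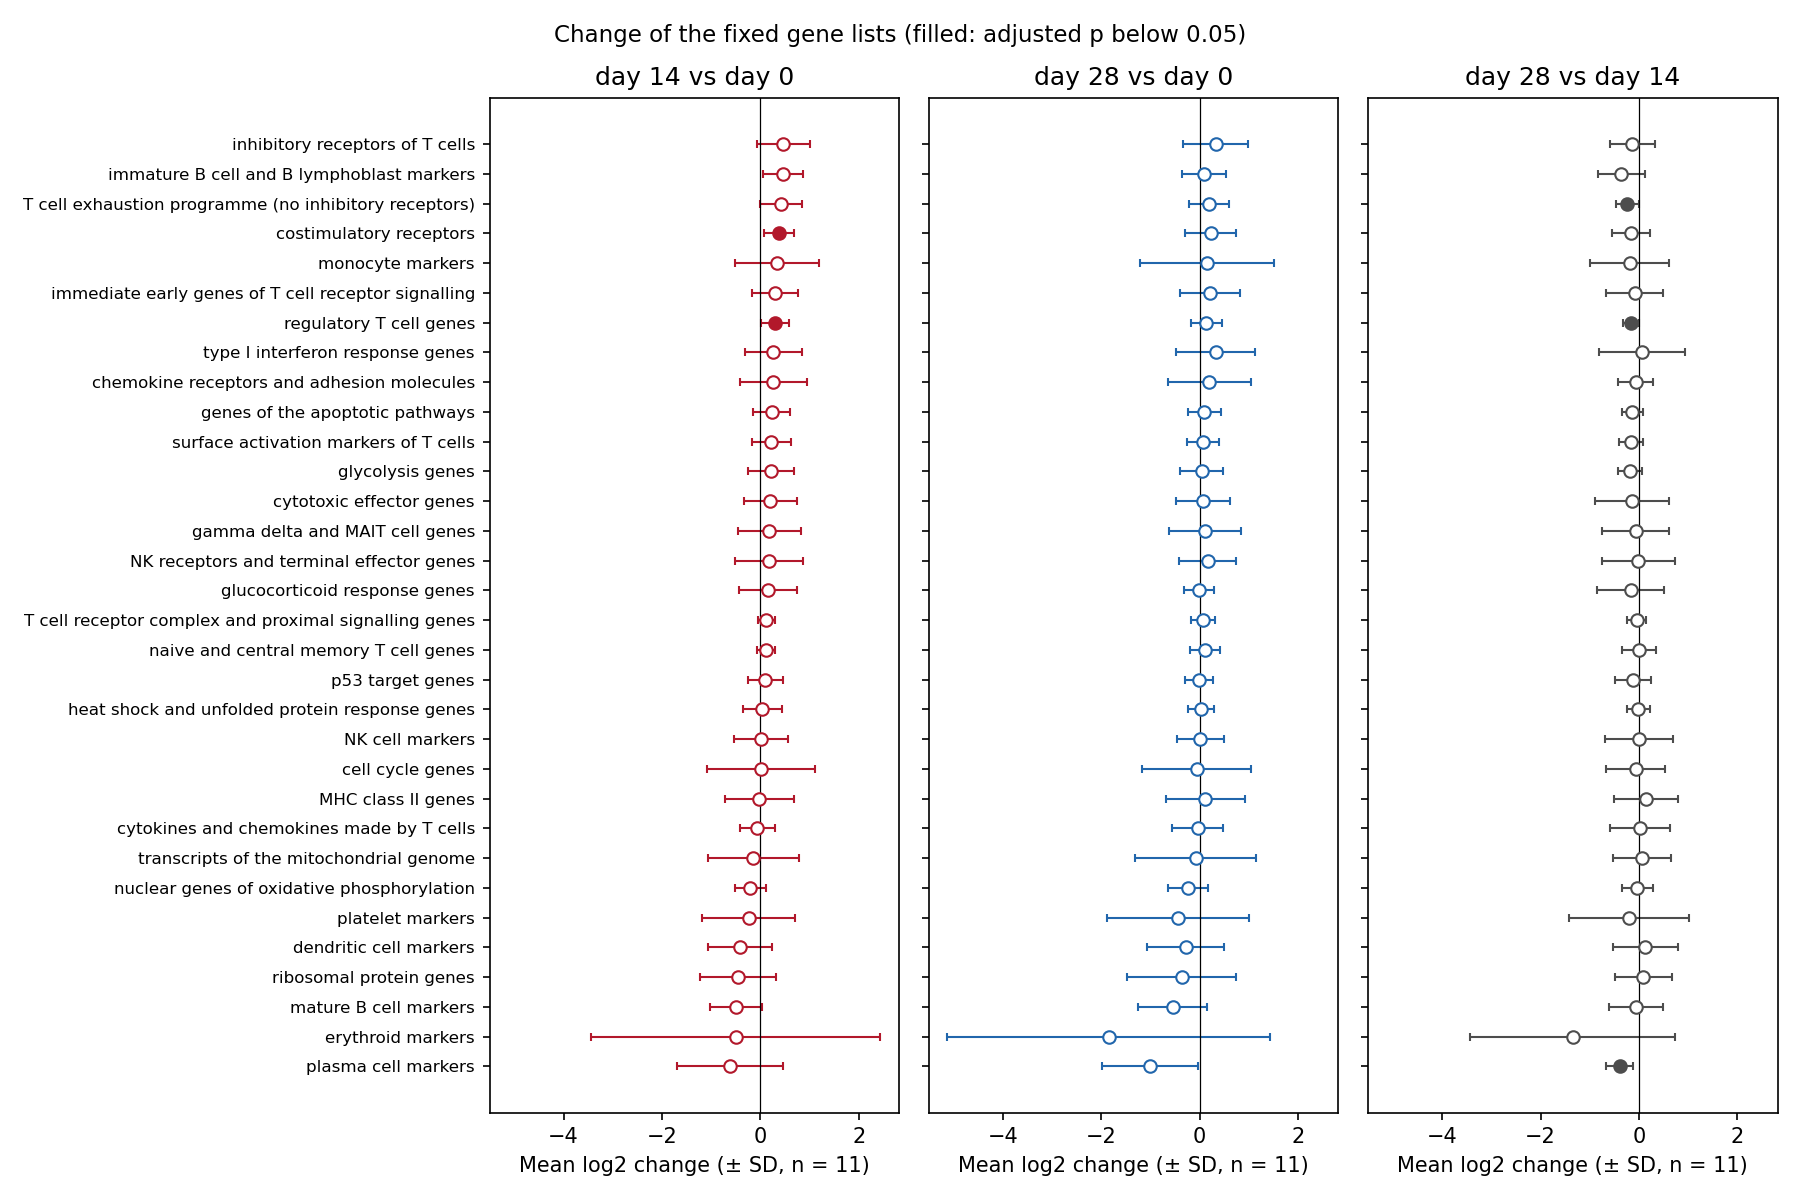
Mean change of the mean log2 CPM of 32 fixed gene lists over 11 patients (horizontal axis, log2 units, bars ± SD), in 3 panels for the 3 comparisons, with filled circles for lists with an adjusted p below 0.05. The regulatory T cell genes (0.30) and costimulatory receptors (0.38) are filled for day 14 vs day 0, and the exhaustion programme (-0.24), regulatory T cell genes (-0.16) and plasma cell markers (-0.39) for day 28 vs day 14, and of these 5 the plasma cell markers alone also passed camera with an estimated correlation.

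The comparison of day 28 with day 14 asked what differed between the later samples. As groups, 3 lists were lower on day 28 by the sign-flip test. In camera the plasma cell markers had an adjusted p = 0.0457 with an estimated correlation, while the exhaustion programme, with an adjusted p = 0.102, and the regulatory T cell genes, with an adjusted p = 0.189, did not pass. The immature B cell and lymphoblast list, at -0.36 ± 0.48 and lower in 8 of 11 patients, also passed that camera test (adjusted p 0.0457). By the sign-flip test it did not (adjusted p 0.219). The exhaustion programme genes fell by a mean log2 of 0.24 ± 0.24 (SD), in 10 of 11 patients (exact p 0.00195, adjusted p 0.0313), with 13 of 16 fold changes negative. IRF4, a factor induced by T cell receptor signals, stood at -0.82 ± 0.21, LAYN at -0.89 ± 0.40, TNFRSF9 at -0.54 ± 0.34 and TOX2 at -0.54 ± 0.29. The regulatory T cell genes fell by 0.16 ± 0.15, in 10 of 11 patients (adjusted p 0.0417), with CTLA4 at -0.58 ± 0.23 and the transcription factor gene IKZF4 at -0.38 ± 0.31. The plasma cell markers fell by 0.39 ± 0.28, in 11 of 11 patients (adjusted p 0.0313), with JCHAIN higher on day 28 in 5 of 11 patients and lower in 5. Immunoglobulin constant region transcripts did not pass the filter, the list's own IGHG1 and IGHA1 among them, and so do not enter its mean. Their summed level differed by 0.93 ± 1.63, higher in 7 of 11 patients (exact sign-flip p 0.0527). Adjusted over the list alone, IRF4 passed in the exhaustion programme and in the plasma cell list, and 0 of 11 regulatory T cell genes did. Of the 6 measured plasma cell members, IRF4 and XBP1 stand also in other lists, while JCHAIN stood at 0.332 and MZB1 at 1.05 CPM on day 28.

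No gene passed edgeR's test between days 28 and 14, 202 genes had an unadjusted p under 0.05, and DESeq2 called NUDT10 alone (1 gene) and limma voom 0. HAVCR2 stood at a log2 fold change of -0.94 ± 0.29, lower in 10 of 11 patients, and CD8A at -0.39 ± 0.18, lower in 10 of 11 (edgeR adjusted p 1.00 for both). Without the libraries of high MALAT1 share the adjusted p was 0.188, 0.0938 and 0.0625 for the exhaustion programme, regulatory T cell and plasma cell lists, where 10 patients remained and the smallest exact p was 0.00195. Without pairing by patient it was 1.00, 1.00 and 0.116, the highest of the alternatives, whose lowest were 0.000474, 0.0208 and 0.000199.

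The balance of CD8 and CD4 transcripts was followed as the log2 ratio of CD8A to CD4, with 1 CPM added to each. It was 1.48 ± 0.71 on day 0 and 0.85 ± 0.88 on day 28 (SD, n = 11). The change was -0.23 ± 0.46 on day 14 (exact sign-flip p 0.128, adjusted p 0.192), with a higher ratio in 3 of 11 patients. On day 28 it was -0.63 ± 0.97 (exact p 0.0576, adjusted p 0.173), with a higher ratio in 4 of 11. Between days 14 and 28 it was -0.40 ± 1.01 (adjusted p 0.229). None of these mean changes within patients passed the sign-flip test at the threshold.

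The changes on days 14 and 28 were set against each other across genes, which are not independent replicates. JCHAIN was called lower on both days, and no gene was called higher on both. The overlap of independent lists would be 6.32e-05, which leaves out the shared day 0 libraries. The log2 changes of the 15817 genes correlated at 0.754 with a covariance of 0.0686. Both comparisons use the same day 0 libraries, and 20 simulations with no change on either day gave 0 shared calls, a mean correlation of 0.507 and a mean covariance of 0.0338, which is 0.0347 below the observed one. The simulations drew every gene and library independently, without differences between libraries such as the MALAT1 share. They therefore cannot tell a change common to both days from such differences among the shared day 0 libraries. When the patients were split into sets of 6 and 5, so that each comparison had its own day 0 libraries, the median correlation over 462 splits was 0.124 (from -0.327 to 0.431).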

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

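Of the tests in this part, the one on held-out patients was written before its result was seen, while the others (day swaps, MALAT1, and monocyte and regulatory T cell markers) were chosen after the counts or values they address were known.

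The difference between days 14 and 28 passed its own paired test for 3 lists. Both days are set against the same day 0 libraries, so this is a test of whether the day 14 and day 28 changes differ. The exhaustion programme genes differed by a mean log2 of -0.24 (adjusted p 0.0313), the regulatory T cell genes by -0.16 (adjusted p 0.0417) and the plasma cell markers by -0.39 (adjusted p 0.0313). In camera with an estimated correlation the adjusted p was 0.102, 0.189 and 0.0457 in that order, so that the first 2 were lost. None of the 3 passed the sign-flip test without the libraries of high MALAT1 share (adjusted p 0.188, 0.0938 and 0.0625), with mean changes of -0.166, -0.15 and -0.335. With the 10 patients left a list cannot pass alone, yet all 3 passed together without replicate 3 and without replicate 6. The number of patients therefore does not by itself account for these losses. The mean changes shrank, and what part the libraries had was not tested. No single gene passed in that comparison.

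Day labels were swapped at random within patients, to make 100 splits with the real one. For day 14 vs day 0 the real split gave 18 genes and the highest other 12, so that 1 of 100 splits, the real one itself, gave as many. At an unadjusted p under 0.05 in edgeR's test, 17 of 99 other splits gave at least the 1255 genes of the real one, up to 2074. So many called genes were thus rare among the splits, while so many small p-values were not, and chance was not excluded. Against day 0, the real day 28 split gave 1 gene, 5 of 100 splits gave as many and the highest other gave 435, so chance cannot be excluded. So many calls in that split point to a structure of the samples. Of the 100 it had the largest difference in mean MALAT1 share between its sides, at 1.88 percentage points against 0.0726 for the real split, while 36 of the 100 had as large a difference along the second principal component, and whether MALAT1 made its calls was not tested. Between days 28 and 14 the real count was 0, so that all 100 splits gave as many, and the highest other was 0.

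The 17 genes that were higher on day 14 had a mean log2 change of 1.49 ± 0.57 (SD over 11 patients). In the 8 patients with neither library over the MALAT1 limit it was 1.44 ± 0.229 (SE). Since the genes were picked with these 8 among the 11 patients, a high mean was favoured in advance. It therefore cannot decide what part the libraries over the limit had. The median fold change of the 17 was 1.22 with a median SE of 0.232, 1.14 with 0.22 without the libraries (7 called) and 1.13 with 0.229 with the MALAT1 share in the fit (15 called); the folds shrank a little and the errors did not grow, fewer libraries leave fewer residual degrees of freedom, and which of these ended the calls was not tested. RNA of monocytes, which the CD3 gate should remove, is argued against for the summed rise of the 12 genes that reached 10 CPM. Their sum rose by 569 ± 81.8 CPM (SE), while that of 13 monocyte markers changed by -56.7 ± 55 CPM, a difference of 626 ± 106 CPM. Among the markers, LYZ stood at 95.0 CPM on day 0 and 109 on day 14, and S100A8 at 73.4 and 40.3. The 12 genes were picked for their rise in these patients, which favoured a large sum in advance. The markers were not picked that way, and their sum showed no rise. A sum weighs abundant genes most, so for single genes such as HAVCR2 monocyte RNA was not tested. For the other 5 (VSIG4, GPC3, MYO1E, MRC2 and SIRPB3P) the sum rose by 21.3 ± 4.95 CPM. Their difference from the markers was 78 ± 55.6 CPM, which leaves monocyte RNA open. Of the 13 markers 9 had positive fold changes (list mean 0.34 ± 0.85, SD). Of the regulatory T cell markers, CTLA4 rose by 1.22, and the median of the other 10 was 0.278 with an SD of 0.276. CTLA4 was picked as the called member, and 5 of the 11 stand also in other lists, so this gap cannot decide on a larger share of those cells. The list as a whole rose in 11 of 11 patients (0.30 ± 0.29, SD). A larger share of regulatory T cells, a change within them and the effect of infusion, disease or other treatment over time stay open.

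All 17 genes had smaller changes on day 28 than on day 14, with a median log2 fold change of 0.65 against 1.22. Genes picked for a high day 14 value would show this by selection alone. In 100 splits, 20 genes were picked in 6 patients, and in the 5 held-out patients their day 14 change exceeded the day 28 change by 0.252 ± 0.0934 (SD over splits, which share patients and so understate the error), at 0.60 against 0.348. A partial return by day 28 remains as a hypothesis, for which no single gene passed the direct comparison and the splits reuse the same 11 patients.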

How the results depend on the processing

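The alternatives without the libraries of high MALAT1 share and with that share as a covariate were chosen after seeing the data. No called value changed direction in any alternative. For day 14 vs day 0 (18 genes), no replicate block gave 3, DESeq2 50 (41 higher), no filter 180 (110 higher), limma voom with sample weights 39, the libraries of the 2 days alone 6 and the set without high MALAT1 shares 9. All 18 were among the calls of DESeq2 and of the unfiltered test, and 17 among those of limma voom. Day 28 vs day 0 (1 gene) had 9 with DESeq2, 75 with no filter, 0 with the stricter filter (where JCHAIN was not tested), 2 with limma voom and 2 without high MALAT1 shares. Day 28 vs day 14 (0 genes) had 1 with DESeq2 and 11 with no filter. Leaving out each patient gave 10 to 27, 1 to 3 and 0 to 0 genes for the 3 comparisons. The lowest of the first came without replicate 4 or 5 and the highest without replicate 2. MYB lost its call without replicate 3, 4, 5, 6, 7, 8 or 10 (adjusted p up to 0.164), CTLA4 without 1, 4, 5 or 7 (0.0841), RAB37 without 4, 5 or 10 (0.0646), MAGEH1 without 5, 7 or 11 (0.0612), HAVCR2 without 4 (0.0561) and C1orf228 without 5 (0.0625), while LAYN, LYST and JCHAIN kept theirs. LYST kept its call in all 21 alternatives. Genes called in both comparisons with day 0 (1) numbered 6 with DESeq2, 62 with no filter, 0 with the stricter filter, 2 with limma voom, 0 with 2 days alone, 2 without high MALAT1 shares, and 1 to 3 with a patient left out. With the patients split into 2 sets it was 0, which says nothing of the overlap because neither set called a gene. Of the lists, 2 passed for day 14 vs day 0. The stricter filter gave 1, scaled members 0, no replicate block 0, camera 15 with a preset and 0 with an estimated correlation, the set without high MALAT1 shares 0, and leaving out a patient 0 to 5. Day 28 vs day 0 (0 lists) had 11 with preset camera and 0 to 0 with a patient left out. Day 28 vs day 14 (3 lists) had 1 with the stricter filter, 1 with scaled members, 0 without the replicate block, 14 with preset camera, 0 without high MALAT1 shares and 0 to 3 with a patient left out. Of the calls of preset camera, 0, 0 and 2 held with an estimated correlation. With 10 patients the smallest exact p is 0.00195, so by construction a list cannot pass alone among 32. The same holds with the 8 patients left for day 14 vs day 0 without high MALAT1 shares, at a smallest exact p of 0.00781. The mean changes of the 2 lists lost there did not shrink, at 0.316 and 0.425 against 0.296 and 0.38. For the other losses the cause was not tested. The CD8A to CD4 ratio kept its direction and did not pass in any alternative, ranging over patients left out from -0.30 to -0.14 on day 14, -0.73 to -0.47 on day 28 and -0.52 to -0.18 between them. Leaving out the replicate block ended the calls of HAVCR2, CTLA4, LAYN, MYB, RAB37, MAGEH1, C1orf228 and the called lists, and changed no other call of a named gene, list or ratio. Over all alternatives, no block included and the patients left out counted as a single alternative at the patient whose p moved most toward the other side of the threshold, named genes kept their side of the threshold 814 times, lost it 27 times and gained it 9 times, and lists did so 697, 25 and 40 times. Of 850 such gene values 52 had a changed sign, none of them a call. Depth limits what can be said of genes near 1 CPM.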

Other observations

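Of the tests in this part, the 2 relations over patients were written before they were computed, and the others were chosen after their values were seen. Genes that DESeq2 and limma voom both called on day 14 but edgeR did not numbered 11. Among them were FGFR1, a fibroblast growth factor receptor gene (edgeR log2 fold change 1.28 ± 0.28, adjusted p 0.0735), HAVCR1, the gene of TIM-1 (1.22 ± 0.30, adjusted p 0.183), SIRPG, a T cell surface receptor that binds CD47 (0.80 ± 0.21, adjusted p 0.228), and GNG8, a G protein subunit gene (1.82 ± 0.43, adjusted p 0.109). All 37 ribosomal protein genes had negative fold changes on both days, with medians of -0.54 on day 14 and -0.37 on day 28. As a list they did not pass on either day (adjusted p 0.18 and 0.693, exact sign-flip test), both days share the day 0 libraries, and without the libraries of high MALAT1 share the list's mean change was -0.11 and -0.10, against -0.46 and -0.37 with them.

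Immunoglobulin transcripts were examined apart from the tested set, because none of 14 constant region genes, IGHM and IGHD not among them, passed the expression filter. Their summed level exceeded 10 CPM in 8 of 11 day 0 libraries, reaching 1910, and in 0 of 11 on day 14 and 0 of 11 on day 28, where the highest reading was 6.21. The median was 15.8 CPM on day 0, 0.0641 on day 14 and 0.0921 on day 28. With 0.1 CPM added, which sets the size of so large a fold, the log2 level fell by 7.30 ± 4.20 on day 14 (SD, lower in 10 of 11 patients, exact sign-flip p 0.00195, adjusted p 0.00586 over 3 comparisons) and by 6.37 ± 4.84 on day 28 (lower in 9 of 11, adjusted p 0.00732). Between days 14 and 28 it differed by 0.93 ± 1.63, higher in 7 of 11 patients (adjusted p 0.0527). IGKC, the kappa light chain, had 22724 counts over the day 0 libraries, 4 over day 14 and 52 over day 28. Its day 0 median was 10.5 CPM, so a few high libraries made up most of the day 0 total.

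In the 8 patients with neither library over the MALAT1 limit the level fell by 6.28 ± 1.44 (SE) on day 14, which argues against the libraries of high MALAT1 share as the whole reason. Of the B cell genes in the tested set, IGHM had medians of 10.4, 2.12 and 1.47 CPM on days 0, 14 and 28, and CD79A, a B cell receptor component, 11.5, 12.0 and 9.72 CPM. Of the 8 measured members of the mature B cell list, which holds both, 6 had negative fold changes on day 14, MS4A1 (-0.96) and FCRL1 (-0.77) among them, and the list did not pass (lower in 10 of 11 patients, adjusted p 0.0688). Effects of the infusion and of sorting purity over time stay open and untested.

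As hypotheses over the 11 patients, 2 relations with the day 14 change of the inhibitory receptor list were written before they were computed. The immunoglobulin level on day 0 had a Pearson r of 0.318 (permutation p 0.342) and a Spearman rho of 0.245 (p 0.467), adjusted p 0.342 and 0.467, and r was 0.177 without the 2 patients farthest from the median, so no relation was shown. The change of the MALAT1 share had an r of -0.595 (permutation p 0.0561, adjusted p 0.112) and a rho of -0.70 (p 0.0196, adjusted p 0.0392), with r at -0.436 without the 2 farthest. The change of the list was higher where the MALAT1 share was lower than on day 0, by rank but not by Pearson's r after adjustment, so a difference between libraries that moves with MALAT1 may carry part of that list's change. The written criterion did not say which coefficient decides, and the question stays open.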
